A study of Mus musculus with 8 samples.

How the data were processed

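RNA was measured by high-throughput sequencing in 8 libraries of mouse mammary cells, 4 control and 4 labelled a3a6KO, and the series design text calls the cells basal and the replicates biological. Per the labels' protocols, tissue explants of mature virgin glands were kept for 1 week in serum with 4-OHT (4-hydroxytamoxifen, the ligand of tamoxifen-inducible Cre recombinase), then digested and sorted by flow cytometry. RNA was taken up on small Qiagen columns, and the libraries were made with the SMARTer v4 protocol, which starts from little RNA. The gates of the sort, the alleles, and whether the control explants carried a recombinase are not given in the sources used here. Each library was placed in its group by its title, which also gives the replicate number.

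Per the submitters' processing notes, the tools named were FastQC, Picard, SAMtools, STAR 2.4.0 and DESeq2, with the genome build mm10; the roles of the tools, the read counter and its use of strand are not given in the sources used here. The authors deposited 1 table of gene signal, in which each value is a read count divided by a size factor for its library, and its columns carry the descriptions of the 8 samples. That reading rests on the values: in each library 100% of the non-zero signal values deposited were whole multiples of 1 step within 0.1 read, and the largest departure was 2.86e-04 read. Dividing by the step gave back the reads, 11561587 to 27893234 per library. Size factors recomputed with DESeq2 from these reads were 0.804 to 0.840 times those deposited, highest in a3a6KO replicate 2. Among gene counts of 1 to 100, between 59.1% and 62.9% were even, where single reads would give close to equal shares of odd and even counts; mates of a read pair counted separately are a possible source, which was not tested. PCR duplicates were also not marked by molecular identifiers, so depth overstates the number of molecules.

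The table held 56440 gene models with the authors' identifiers, symbols and mm10 coordinates, 30655 of them without a symbol, and 34360 blank lines that were left out. Models without a symbol took 2.61% to 3.73% of the values of a library, and genes of the mitochondrial chromosome 0.445% to 1.20%. Where a row joined a gene with a microRNA or snoRNA inside it, the row was read as that gene; rows shared by several other genes stayed out of the gene lists. No pair of libraries agreed within sampling noise (lowest chi-square per degree of freedom 18.7 over all pairs), so no library was taken as a copy of another's reads. Amplified reads can exceed that noise, so the value does not show that the samples were separate. Each library counted as a replicate because the series design text calls the replicates biological. Strand, and genes overlapping on the opposite strand, were looked up in the GENCODE M21 annotation of the same genome, where 120 of 120 genes looked up matched by symbol and overlapping place, 10 of them with the same start and end. The row of Top2a starts at 98937373 of chromosome 11, before the annotated start of the gene at 98992943, so it can hold reads from outside it. Of the 120 genes, 43 have an annotated gene on the opposite strand within their bounds, and reads of such partners cannot be told apart without strand; among the genes named as changed this concerns Kcnq1, Dnajb9, Pdk2, Tnfsf9, Kcnh1, Adamts4, Top2a, Cmah and Slc7a5, and among those that passed only with the replicate block Col4a6, Trp63, Cldn3, Marveld2, Cdkn1a, E2f8, Kif11, Prc1, Wnt7b, Ccnd1, Ltbp2, Dusp1, Psat1, Slc7a11 and Pnpla8. Some genes named only in the closing observations were not looked up.

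The main test was fixed before the data were examined: limma 3.58.1 with its intensity trend in R 4.3.3, on log2(deposited value + 1), for the 14578 genes with a mean value of at least 10 over the 8 libraries, of which 1670 had no symbol. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. All log2 fold changes are a3a6KO minus control on the log2(value + 1) scale, which understates the change of genes with low values. Groups are given as mean ± SD of deposited values with n = 4, and fold changes with the standard error of limma. Depth varied between libraries, and 3 reads correspond to values between 1.38 and 3.33, so differences of a few units between low values are within counting error. In this test, the p-value of a gene measures the spread between these cultures.

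Gene lists fixed before the data were examined numbered 28: integrin subunits, laminins and basement membrane, hemidesmosome and focal adhesion, basal and myoepithelial identity, luminal keratins and junctions, luminal progenitor and milk genes, hormone-sensing luminal genes, squamous and wound keratinocyte genes, p53 targets, S phase and replication, G2 and mitosis, YAP and SRF targets, Notch pathway, Wnt pathway, TGF-beta and mesenchymal transition, extracellular proteases, NF-kB and chemokines, interferon response, immediate early genes, unfolded protein and integrated stress response, hypoxia and glycolysis, cholesterol synthesis, markers of fibroblasts, endothelial cells and pericytes, leukocytes, adipocytes, and Schwann and neural cells, and 1 list that entered the tests and counts but, like some single genes, is not reported here. They held 734 genes, of which 13 had no row of their own. The 27 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, which asks whether a list moves more than other genes, with Benjamini-Hochberg adjustment over the lists. The preset treats the members of a list as nearly independent, so these p-values do not measure the spread between cultures. None of the calls held when the correlation was estimated from the data. Named genes followed a rule fixed at the same time: Itga3, Itga6, Itgb1 and Itgb4; up to 12 called genes in each direction with the largest change, a mean value of at least 50, no overlap between the groups and a proper gene name; up to 4 called members of each list, or up to 2 of its most abundant members. Members named because they passed only with the replicate block, and other members given as examples, were chosen after their values were seen.

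Control and a3a6KO libraries share replicate numbers in their titles. The deviations of same-numbered libraries from their group means correlated at 0.19 to 0.38 across genes, above 0.1 in all 4 pairs. Those of differently numbered libraries ranged from -0.37 to 0.38, with a mean that the centring on group means ties to the same-numbered one, and 4 of 8 libraries correlated best with their own number. By a criterion of a correlation above 0.1 in every pair, the numbers were taken to pair the libraries. That criterion does not single out equal numbers. Control replicate 2 correlated at 0.378 with a3a6KO replicate 4 and at 0.219 with its own number. Control replicate 4 correlated at 0.239 with a3a6KO replicate 2 and at 0.189 with its own number. Pairing by number is therefore an assumption of the block. Values from a fit with the replicate number as a block stand beside results whose call they change.

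Alternatives were another pseudocount (0.5 or 8), no filter or a minimum mean of 50, equal column totals, TMM or quantile scaling, robust variance moderation, sample quality weights, the replicate block, leaving out each library, and, on the recovered reads, edgeR 4.0.16 and DESeq2 1.42.0. Lists were also tested with an estimated correlation and with fry. Alternatives added after seeing the data left out both replicate 3 libraries or set the block together with another tool.

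The fits were tested on simulated data before use, with counts drawn from the real means and depths and 200 genes changed 2-fold or 4-fold. Tested members of the G2 and mitosis list outside those 200 were lowered 2-fold as well. Shares recovered are given for the 200. With no effect shared by pairs, limma recovered 42% of the genes changed 2-fold and 90% of those changed 4-fold among 14396 genes tested, and 2.74% of its calls were genes left unchanged; for DESeq2 that share was 19.2%, and 5.06% with effects shared by pairs. With effects shared by pairs, limma recovered 11% and 92%, and with the block 58% and 96%, but 10.4% of the calls with the block were then unchanged genes. The simulated pair effects followed the replicate numbers exactly, so the gain with the block depends on that setting. It does not show that the real libraries pair by number. Camera called the 1 list that had been changed and none of the other 26. The simulated genes varied independently of each other, while estimated correlations within the real lists reached 0.90. The simulation therefore decides nothing about camera calls for lists whose members vary together.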

Results

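Gene expression was compared between control mouse mammary basal cells and basal cells labelled a3a6KO, with 4 libraries of each. The label names Itga3 and Itga6, which encode the α3 and α6 subunits of integrins that bind laminin in the basement membrane. The titles of the a3a6KO libraries also mark the cells as a6neg. The series title places the experiment in a study of the mammary stem cell niche, and the comparison asks how gene expression differs between these basal cells, cultured within tissue explants. Recovered reads numbered 17052499, 13319611, 15341509 and 12640224 for control replicates 1 to 4 and 11561587, 27893234, 15126781 and 16120877 for a3a6KO replicates 1 to 4. Between 21377 and 23512 gene models had a value above 0 in a library.

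Itga3 (GSMG0007263, chromosome 11, 95044476 to 95076811 of mm10, minus strand) was reduced in every a3a6KO library. Its normalised value fell from 2663 ± 540 in control to 381 ± 108 in a3a6KO (SD, n = 4), 7.11-fold, with a log2 fold change of -2.83 ± 0.23 (SE) and a limma adjusted p of 0.00113. Itga6 (GSMG0021209, chromosome 2, 71786928 to 71858427, plus strand) had 10097 ± 1443 in control and 6725 ± 1642 in a3a6KO. Its groups did not overlap and it was lower in 4 of 4 replicate pairs, but the log2 fold change of -0.61 ± 0.18 did not pass the test (limma adjusted p = 0.197; 0.0809 with the replicate block). The table holds 1 value per gene, and which exons the alleles remove is not given in the sources used here, so reads from exons that remain count towards both values. The partner subunits Itgb1 (50946 ± 4084 and 47046 ± 2741) and Itgb4 (6944 ± 2302 and 5316 ± 1166) changed by -0.11 ± 0.13 and -0.34 ± 0.25 on the log2 scale, within the spread between replicates.

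**Figure D1:**
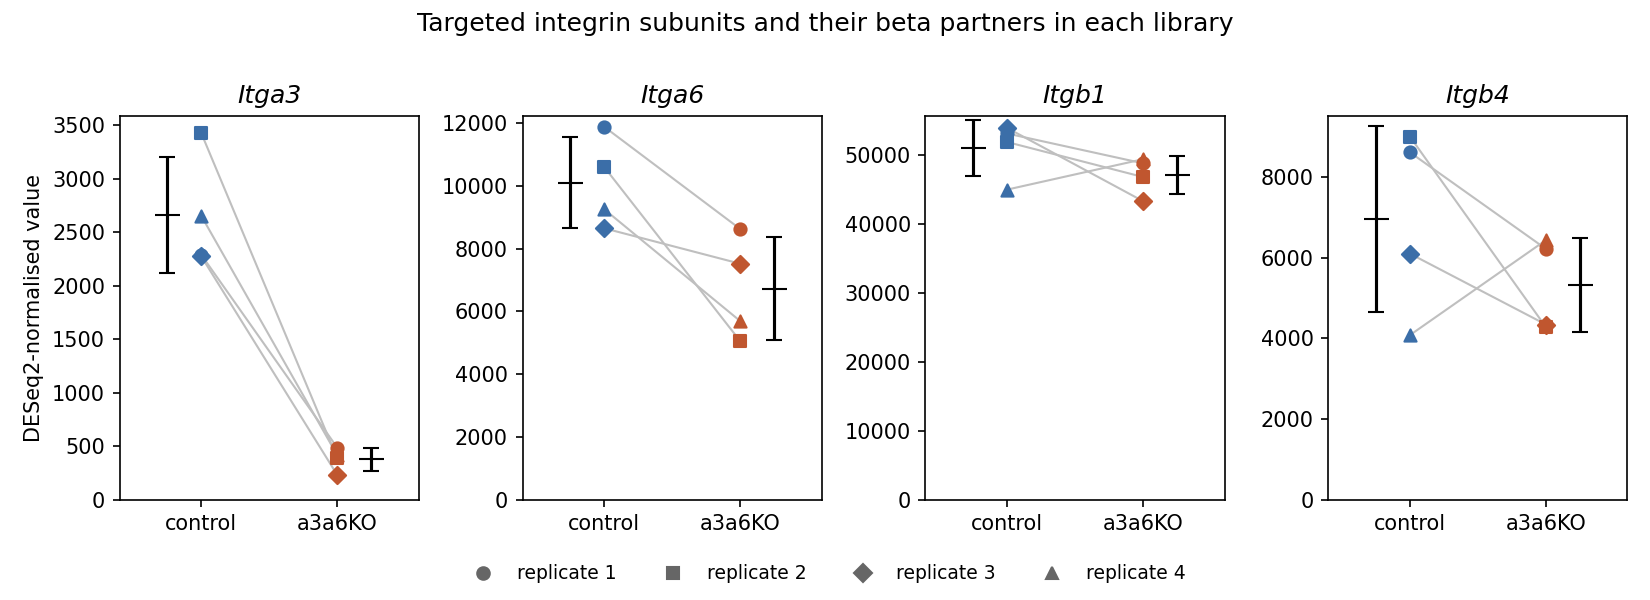
Deposited DESeq2-normalised values of Itga3, Itga6, Itgb1 and Itgb4 in the 8 libraries, on linear axes from 0; each point is a library, its shape gives the replicate number, grey lines join equal numbers, and black marks give the mean ± SD of 4 libraries. Itga3 falls from a mean of 2663 to 381, Itga6 has means of 10097 and 6725 without overlap, and the groups overlap for Itgb1 and Itgb4.

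The largest rise was that of Nrcam, which encodes a cell adhesion molecule of the immunoglobulin family best known from neurons. It went from 15.6 ± 12.1 in control to 4854 ± 1731 in a3a6KO, a log2 fold change of 8.48 ± 0.53 (limma adjusted p = 2.54e-04). Dnajb9, which encodes a co-chaperone of the endoplasmic reticulum, rose 9.34-fold from 72.2 ± 10.9 to 722 ± 327 (log2 fold change 3.22 ± 0.26, limma adjusted p = 0.00113). Both genes lie on chromosome 12, Dnajb9 (GSMG0008832) at 44205895 to 44210069 on the minus strand and Nrcam (GSMG0008034) at 44328885 to 44601964 on the plus strand, 118815 bp apart. Pnpla8, the tested gene between them, had 456 and 265 (log2 fold change -0.77, limma adjusted p = 0.0591; 0.0377 with the replicate block), in a row it shares with Gm2027. Stxbp6, the next tested gene beyond Nrcam, had 27.5 and 26.7 (log2 fold change -0.07).

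**Figure D2:**
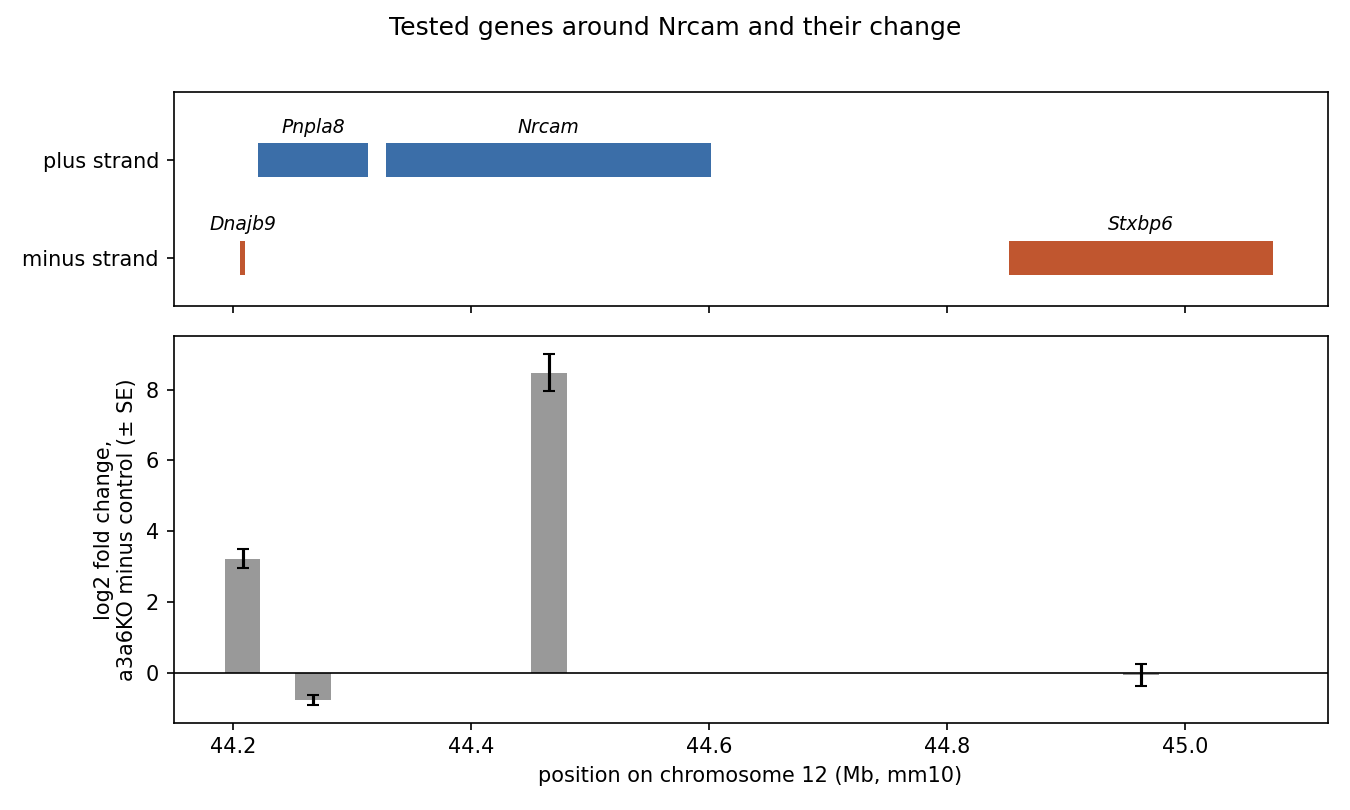
Top, tested genes of chromosome 12 around Nrcam (position in Mb of mm10), drawn to scale by strand; bottom, log2 fold change (a3a6KO minus control) of each gene at the middle of its span, with bars for ± SE from 4 libraries per group. Dnajb9 (3.22) and Nrcam (8.48) rise, Pnpla8 between them is at -0.77 and Stxbp6 at -0.07.

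Other genes that rose included channels, membrane proteins and secreted factors. Kcnq1, a potassium channel gene, rose from 8.99 ± 4.18 to 149 ± 90.6 (log2 fold change 3.85 ± 0.45, limma adjusted p = 0.0126); the antisense transcript Kcnq1ot1, which lies within it, had 66.8 in control and 52.8 in a3a6KO (adjusted p = 0.627). Kcnh1, another potassium channel gene, rose from 57.2 to 153. Ly6d rose 3.92-fold to 87.8 ± 24.1, and Mal, a raft-associated protein of apical sorting, rose from 25.9 to 103. Tnfsf9, the ligand of the co-stimulatory receptor 4-1BB, rose from 107 to 280, Megf6 from 91.3 to 286, and Wisp1, a matricellular protein of the CCN family, from 536 to 1174. Afap1l2 and the peroxisomal oxidase Acox2 had log2 fold changes of 1.17 and 1.15. Pdk2, a kinase that inhibits pyruvate dehydrogenase, rose from 261 ± 74.8 to 781 ± 88.9 (log2 fold change 1.62 ± 0.20, limma adjusted p = 0.0174). It lies on the same strand as Itga3, 3104 bp downstream of its end.

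Among the genes that fell, Dsc3, a desmosomal cadherin, fell from 284 ± 47.6 to 86.5 ± 39.5 (log2 fold change -1.78 ± 0.27, limma adjusted p = 0.0346). Gja1, which encodes the gap junction protein connexin 43, fell from 16947 ± 1414 to 8935 ± 283 (log2 fold change -0.92 ± 0.11, adjusted p = 0.0126). The amino acid transporters Slc7a3, Slc1a5 and Slc7a5 fell by 1.49, 0.99 and 0.88 on the log2 scale, and Mthfd2, of mitochondrial one-carbon metabolism, fell by 0.72. Slc27a6, a fatty acid transporter, fell from 125 to 45.08 and Ptn, the growth factor pleiotrophin, from 984 ± 122 to 405 ± 88.8. Cmah, a hydroxylase of sialic acid, fell from 631 to 314. Top2a and Anln, of chromosome segregation and cytokinesis, fell by 1.11 each.

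In all, 38 of 14578 genes passed limma at an adjusted p under 0.05, 24 higher and 14 lower in a3a6KO, and 1880 had an unadjusted p under 0.05. With the replicate block 314 genes passed, 183 higher and 131 lower, and these included all 38. None of the 38 had overlapping groups, which rests on the same values as the calls and is no separate support. Over all tested genes 8.25% had no overlap, where interchangeable libraries and no difference would give 2.86%. Same-numbered libraries may not be interchangeable and genes vary together, so these shares are not a test. The count was 8, 11, 35 and 6 without control replicates 1 to 4 and 45, 8, 10 and 4 without a3a6KO replicates 1 to 4, and 3 genes, Itga3, Nrcam and Dnajb9, were called whichever library was left out. Of the other tools, edgeR called 29 genes, all among the 38, while sample quality weights in limma gave 632. DESeq2 was run on the 29966 genes with any read, without the filter on the mean value, and called 436, which included the 38.

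Genes of cell division were lower in a3a6KO as a group. All 36 tested members of the G2 and mitosis list had negative changes, with a median log2 fold change of -0.92. Top2a (220 ± 27.7 to 101 ± 3.35) and Anln (854 ± 123 to 397 ± 76.0) fell, and 34 members did not pass; adjusted over the list alone, 33 passed. With the replicate block 22 members passed, among them Tpx2, Kif11, Prc1 and Bub1 with log2 fold changes of -0.91, -0.99, -0.96 and -1.11 (limma adjusted p = 0.0125, 0.0173, 0.0192 and 0.0204). Camera placed the list below other genes (adjusted p = 1.61e-26), with an adjusted p = 0.374 with an estimated correlation. The S phase and replication list fell too, with a median of -0.49 and 33 of 34 members negative (camera adjusted p = 3.42e-12; adjusted p = 0.374 with an estimated correlation). No member of that list passed over all genes and 4 passed adjusted over the list alone, while 5 passed with the replicate block, of which Rrm2 (963 and 550), E2f8 (341 and 176), Uhrf1 (471 and 296) and Mcm6 (685 and 440) had the smallest p. Its most abundant members, Rrm1 and Mcm7, had log2 fold changes of -0.18 and -0.19. The G2 and mitosis score was lower in a3a6KO than in control of the same number in all 4 pairs, and lowest, at -1.06, in a3a6KO replicate 3, the library with the highest scores for fibroblast and leukocyte markers.

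**Figure D3:**
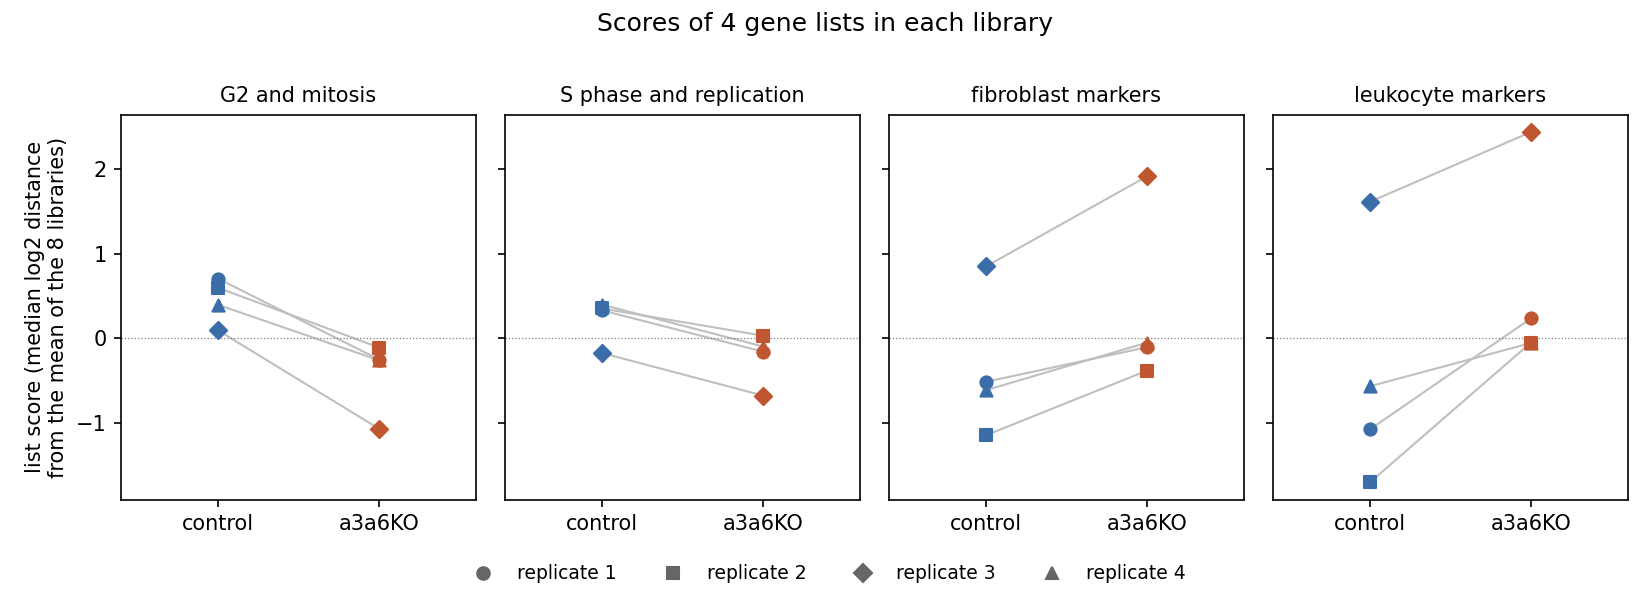
Scores of 4 gene lists in the 8 libraries: the median over tested members of log2(value + 1) minus the gene's mean over all libraries, on a shared linear axis; shapes give the replicate number and grey lines join equal numbers. The scores for G2 and mitosis and for S phase and replication are lower in a3a6KO in each pair, and both replicate 3 libraries have the highest fibroblast and leukocyte scores of their group, 0.85 and 1.91 for fibroblasts.

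Among the integrin subunits only Itga3 passed the unblocked test. Of 17 tested members 7 had positive and 10 negative changes, and the list did not pass camera (median -0.20, adjusted p = 0.375); adjusted over the list alone, 2 were higher and 3 lower. Itgb5 had 4212 ± 1184 in control and 8621 ± 1124 in a3a6KO, and Itga11 124 ± 67.9 and 447 ± 345; both passed with the replicate block (limma adjusted p = 0.0282 and 0.0219) and not without it (0.0681 and 0.327). The hemidesmosome and focal adhesion list, which anchors cells to the basement membrane, was lower as a group, with 20 of 23 members negative and a median of -0.21 (camera adjusted p = 0.00122; adjusted p = 0.374 with an estimated correlation). None of its members passed over all genes, while 1 higher and 4 lower members passed adjusted over the list alone; the most abundant, Actn4 and Ilk, had changes of 0.04 and -0.10. Laminins and basement membrane genes did not pass (median -0.03, adjusted p = 0.3503; median 0.05, adjusted p = 0.470 without a3a6KO replicate 2; with no member called over all genes or adjusted over the list alone); Col18a1 had 53214 and 52983, Sparc 44182 and 55882, and Col4a6, at 659 and 411, passed with the replicate block (adjusted p = 0.0348). The YAP and SRF targets had a median of -0.07 (adjusted p = 0.277), with 0 members called over all genes or adjusted over the list alone. Thbs1 and Ctgf had changes of -0.41 and -0.37.

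Luminal keratin and junction genes were higher as a group in the a3a6KO libraries. Of 22 tested members 16 had positive changes, with a median of 0.22 (camera adjusted p = 0.0104; adjusted p = 0.374 with an estimated correlation). No member passed over all genes, and adjusted over the list alone 6 were higher and 1 lower. With the replicate block the tight junction genes Ocln (196 and 461), Cldn3 (3171 and 6162), Cldn7 (408 and 868) and Marveld2 (112 and 189) passed (limma adjusted p = 0.0215, 0.0251, 0.0424 and 0.0475). Krt8 and Krt7, the most abundant members, had changes of 0.19 and 0.76. The basal and myoepithelial list did not pass (median -0.13, mean 0.06, camera adjusted p = 0.494; median 0.02 without control replicate 1 and 0.00292 without a3a6KO replicate 4; 0 members called either way); Acta2 and Krt17 had changes of -0.33 and -0.32. Trp63, the basal transcription factor p63, had 1664 and 1047 and passed with the replicate block (adjusted p = 0.0340). Only the a3a6KO titles mark the cells as a6neg, and the gates of the sort are not given. A different mix of sorted cells therefore cannot be told apart from a change within basal cells.

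Other epithelial programs did not pass as groups. Luminal progenitor and milk genes had a median of 0.08, or -0.10 without control replicate 2, and a mean of -0.01 (camera adjusted p = 0.494), with 0 members called, and 5 higher and 1 lower adjusted over the list alone. Trf had 8539 and 28390, Mfge8 8315 and 12274.5, Lcn2 4419 and 12028, and Csn1s1 19.8 and 2.93; Trf, Lcn2 and Csn1s1 passed with the replicate block (adjusted p = 0.0251, 0.0348 and 0.0308). The hormone-sensing list had a median of 0.16, or -0.10 without control replicate 3, while camera gave the direction down (adjusted p = 0.9702, 0 members called either way); Stc2 and Ly6a had changes of -0.17 and 1.10. In the squamous and wound keratinocyte list (median -0.37, adjusted p = 0.0856) Ly6d rose and Dsc3 fell, and adjusted over the list alone 1 was higher and 2 lower. Dsg3, another desmosomal cadherin, had 2532 ± 713 and 697 ± 419 and passed with the replicate block (adjusted p = 0.0220; 0.0521 without). That list passed without a3a6KO replicate 1 (median -0.45, adjusted p = 0.0263).

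Among stress and metabolic lists, p53 targets were higher and cholesterol synthesis genes lower. Of 35 tested p53 targets 26 had positive changes (median 0.20, camera adjusted p = 0.0206; adjusted p = 0.632 with an estimated correlation). No member passed over all genes and 4 did adjusted over the list alone. With the replicate block Fas (284 and 517), Ephx1 (2032 and 3310), Btg2 (1541 and 2236) and Cdkn1a, the p21 cell cycle inhibitor (6718 and 9395), passed (limma adjusted p = 0.0215, 0.0322, 0.0417 and 0.0496), while the most abundant members, Perp and Plk2, had changes of -0.37 and -0.46. The p53 call was lost without control replicate 1 (median 0.06, adjusted p = 0.325), a3a6KO replicate 2 (0.10, 0.0542) or a3a6KO replicate 4 (0.14, 0.0682). In the cholesterol synthesis list 22 of 24 members had negative changes (median -0.26, camera adjusted p = 5.60e-04; adjusted p = 0.632 with an estimated correlation), with none called over all genes or adjusted over the list alone; Sqle had a change of -0.26. Its call was lost without a3a6KO replicate 3 (median -0.12, adjusted p = 0.0639), the library with the lowest score.

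The unfolded protein and integrated stress response list was lower (median -0.11, 21 of 27 members negative, camera adjusted p = 0.0106; adjusted p = 0.374 with an estimated correlation), and its called members went both ways. Dnajb9 rose, while Slc7a5 and Mthfd2, which serve amino acid uptake and one-carbon metabolism, fell; adjusted over the list alone, 2 were higher and 7 lower. With the replicate block Cth (553 and 199), Psat1 (1176 and 631), Phgdh (1489 and 914) and Slc7a11 (45.8 and 15.3), of cysteine and serine supply, also passed (limma adjusted p = 0.00747, 0.0221, 0.0340 and 0.0348). The list's call was lost without a3a6KO replicate 1 (median -0.07, adjusted p = 0.0780). Hypoxia and glycolysis genes did not pass (median -0.12, adjusted p = 0.158, 0 called, 1 higher adjusted over the list alone) except without control replicate 2 (median -0.17, adjusted p = 0.0106). Pkm and Ldha had changes of -0.01 and -0.28, and Slc16a3, the lactate exporter, at 1662 and 1026, passed with the replicate block (adjusted p = 0.0458).

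The extracellular protease list, which also holds Timp genes and serpins, was higher as a group (median 0.32, 20 of 29 members positive). Camera gave an adjusted p = 0.0439, and an adjusted p = 0.374 with an estimated correlation. Adamts4, an aggrecan-cleaving protease, rose from 990 ± 185 to 2106 ± 259 (limma adjusted p = 0.0219); adjusted over the list alone, 4 were higher and 1 lower. Of the serpins, Serpine2 (1558 and 3183) was higher with the block, and Serpinb5 (3970 and 2129) and Serpinb2 (426 and 74.4) were lower (adjusted p = 0.0418, 0.0165 and 0.0251). The list's call was lost without control replicate 1 (median 0.21, adjusted p = 0.169), a3a6KO replicate 3 (0.29, 0.0753) or a3a6KO replicate 4 (0.36, 0.0682).

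Signalling lists did not pass camera without the block. TGF-beta and mesenchymal transition genes had a median of 0.22 (adjusted p = 0.0620; 0.01004 with the replicate block), and immediate early genes a median of 0.22 (0.0631; 0.0383 with the block). For both lists the block gave an adjusted p = 0.309 with an estimated correlation. The Wnt pathway had a median of 0.21 (adjusted p = 0.0685), the Notch pathway 0.04 (0.375), and NF-kB and chemokines 0.19 (0.153). None of their members passed over all genes; adjusted over the list alone 4 immediate early genes and 1 Wnt gene were higher, 1 Notch gene was lower, and 0 passed in the other lists. With the replicate block Wnt7b (930 and 2050), Sfrp1 (437 and 979), Dkk2 (93.7 and 36.4) and Ccnd1 (934 and 624) passed in the Wnt list, Id3 (646 and 1513), Id1 (140.5 and 357) and Ltbp2 (6702 and 12200) in the TGF-beta list, Dusp1 (936 and 2128) and Ier3 (3829 and 6656) in the immediate early list, and Jag1 (12304 and 6320) in the Notch list. Of the most abundant members, Fn1 and Postn had changes of -0.46 and -0.05, Fzd7 and Lgr4 of 0.36 and 0.05, Notch1 of 0.24, Csf1 and Ptgs2 of -0.27 and -0.14, and Jun of 0.07. Leaving out single libraries brought TGF-beta (adjusted p = 0.0382 without control replicate 3 and 0.0133 without a3a6KO replicate 2), Wnt (0.0277 without control replicate 1 and 0.0486 without a3a6KO replicate 2), NF-kB (0.0121 without control replicate 2 and 0.0176 without a3a6KO replicate 1) and immediate early genes (0.0311 and 0.0104 without control replicates 2 and 4, 0.00454 without a3a6KO replicate 1) past the threshold. Without a3a6KO replicate 3 the immediate early median was -0.00966 (adjusted p = 0.333) and the Notch median -0.02.

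The list scores of fibroblast, leukocyte, endothelial and pericyte, adipocyte, and Schwann and neural markers were highest in the replicate 3 library of each group, though not every marker was. Col1a1, the main fibroblast collagen gene, had 6292 in control replicate 3 against 332 to 371 in the other controls, and 13088 in a3a6KO replicate 3 against 381 to 787 in the other a3a6KO libraries. Fibroblast markers had a median of 0.44 (camera adjusted p = 0.162; 0.0330 with the replicate block, where the adjusted p = 0.395 with an estimated correlation), with 0 of 15 called and 2 adjusted over the list alone; Col6a1 (150 and 636) and Col6a2 (24.2 and 93.8) passed with the block (limma adjusted p = 0.0130 and 0.0326), and Fbln2, highest in replicate 1 of each group (28778 and 49510), had a change of 0.31. Without a3a6KO replicate 3 the fibroblast median was -0.08, and the list passed without control replicate 3 (0.54, adjusted p = 0.0258) or a3a6KO replicate 2 (0.62, 0.0486). All 10 tested leukocyte markers had positive changes (median 1.05, camera adjusted p = 0.0104; adjusted p = 0.374 with an estimated correlation), 0 were called over all genes or adjusted over the list alone, and the list's call was lost without a3a6KO replicate 3 (0.58, adjusted p = 0.0753); Lyz2 had 101 ± 138 and 193 ± 319, and H2-Ab1 91.4 and 187.

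Interferon response genes were higher as a list (27 of 28 positive, median 0.66, camera adjusted p = 0.0436; adjusted p = 0.680 with an estimated correlation), with 0 called over all genes or adjusted over the list alone. B2m had 8086 ± 7177 and 9363 ± 3691, and Bst2 1192 ± 1497 and 1984 ± 1348; the list's score was 1.58 and 1.46 in the replicate 3 libraries and -2.03 in control replicate 2. Without control replicate 2 its median was -0.00446 (adjusted p = 0.997), and the call was also lost without control replicate 4 (0.44, 0.19999), a3a6KO replicate 1 (0.60, 0.0559) or a3a6KO replicate 3 (0.22, 0.661). Endothelial and pericyte markers (median -0.18, adjusted p = 0.196; median 0.18, adjusted p = 0.609 without control replicate 3; 0 members called either way) and adipocyte markers (median 0.06, adjusted p = 0.506, 0 called and 1 higher adjusted over the list alone) did not pass; Eng and Cspg4 had changes of 0.08 and -0.38, and Pnpla2 and Slc2a4 of 0.47 and -0.47. Only 4 Schwann and neural markers were tested, too few for camera; their median was 0.98, 0 were called and 3 were higher adjusted over the list alone. Of these, Pmp22 had 1531 ± 276 and 4057 ± 1369 and passed with the replicate block (adjusted p = 0.00987), and Cnp had 625 and 945.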

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

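The splits of the libraries and the tests on cell division genes and on replicate numbers were set out before their results were seen; the alternative without both replicate 3 libraries was added after seeing the data. Among 298 groups of 4 values examined for a library far from the other 3, 31 held one, and 20 of the 31 were replicate 3 libraries. Chance gives about 1 in 20, or 14.9, for independent groups of normally distributed values. These groups include list scores beside members of the same lists, so the counts are not a test against chance.

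In control replicate 3, Col1a1 (6292), B2m (18844) and Bst2 (3425) and the endothelial and pericyte score (1.81) lay far above the other controls, and Top2a (179), Uhrf1 (311), Pkm (37668) and the S phase and replication score (-0.17) far below. In a3a6KO replicate 3, Col1a1 (13088), Lyz2 (671), Col6a2 (196), Lcn2 (23258), Sfrp1 (1769), Cnp (1251) and Dnajb9 (1206) and the fibroblast (1.91) and leukocyte (2.43) scores lay far above the other a3a6KO libraries, and Ptn (273), Rrm1 (1940) and the G2 and mitosis score (-1.06) far below. In a3a6KO replicate 1, Acta2 (166613), Perp (18591), Dsc3 (145), E2f8 (235) and Slc2a4 (1190) lay far above the others of the group, and in a3a6KO replicate 4 Slc1a5 (430) far below. Among the other controls, Megf6 (102) and the share of values from models without a symbol (3.37%) were high in replicate 1, Dsg3 (3590) and the YAP and SRF score (0.30) in replicate 2, and the integrin score (-0.33) was low in replicate 4.

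Lower expression of G2 and mitosis genes in a3a6KO was weighed against depth, the stromal RNA of the replicate 3 libraries and the grouping of samples. After every library was thinned to the reads of the shallowest the list's median was -0.90, and without both replicate 3 libraries it was -0.78, with all 36 members negative each time, so neither accounts for the whole difference. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave a median that far from 0 (0.92, highest other 0.74); among the 8 that part all 4 replicate pairs the highest other was 0.55, and 8 splits are too few for a share under 0.05. What stays open is chance among splits that keep the pairing, the genotype, together with anything else that differed between the cultures of the groups, such as cell density or the gate of the sort, neither of which was tested. The estimated correlation among the list's genes is 0.73, and the cause of the call's loss with that correlation was not tested.

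Libraries with the same number deviated together, though replicates 2 and 4 of each group correlated best with the other of these numbers. A shared day, animal batch or processing step that the labels do not name may be the source. Without both replicate 3 libraries the mean correlation of same-numbered libraries was 0.213 and the lowest of the 3 was 0.0888; the excess of that mean over the others, 0.316, is tied to it by centring on group means, so it is no separate evidence and decides nothing. Without the fibroblast, leukocyte, endothelial and interferon lists and the 1000 genes closest to the fibroblast score, 1023 genes in all, the lowest same-number correlation was 0.15. That value argues against these genes as the only source; the other RNA of the replicate 3 libraries and what the pairs share stay open.

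The counts of calls were set against the other splits. For the genes past the threshold (38), 2 of 35 splits gave as many, the real one included, and the highest other gave 119; for genes higher (24) and lower (14) the count was likewise 2, with 63 as the highest other. Chance is therefore not excluded by that count alone. The split with 119 sets replicates 1 and 3 of both groups against replicates 2 and 4, which keeps every pair together and points to a structure of the samples. Among the 8 splits that part all 4 pairs, as the real one does, the highest other gave 0 genes, and with the replicate block the real split gave 314 and the highest other 0; 8 splits are too few for a share under 0.05. For gene lists past the threshold (10), 15 of 35 splits gave as many, with 16 as the highest other and 12 among those that part all pairs, so chance is not excluded for the number of lists; with the block the real split gave 13 and the highest other 11.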

How the results depend on the processing

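Every one of the 38 calls kept its sign under each alternative in which its gene was tested, and the median log2 fold change of all genes, 0.00934 as planned, was -0.00309, -0.00485 and -0.00797 with 3 other scalings. Of the 25 named genes called, 23 to 25 stayed past the threshold with another pseudocount or a higher filter, with robust moderation, with sample weights or with the replicate block, 22 without a filter, and 21 or 22 with equal column totals, TMM or quantile scaling; edgeR kept 20 and DESeq2 all 25. Without 1 library 3 to 18 of them stayed, fewest without a3a6KO replicate 4 and most without a3a6KO replicate 1. Each of these fits lacks 1 library, so fewer samples alone do not account for that range.

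The genes past the threshold numbered 632 with sample quality weights (350 higher, 282 lower), 436 with DESeq2 (231 and 205), 314 with the replicate block (183 and 131), and 4 to 45 without 1 library (2 to 27 higher, 2 to 18 lower). Alternatives added after seeing the data gave 7 (5 and 2) without both replicate 3 libraries, 76 (54 and 22) with the replicate block as well, 297 (169 and 128) with edgeR and the block, and 709 (381 and 328) with DESeq2 and the block. Of the 38, 22 were among the 76 and 7 among the 7. The block removes variation that same-numbered libraries share. The cause of the higher counts with weights and DESeq2 was not tested. For the named genes and lists the block changed no call other than those given with it in the results or in the other observations below.

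Itga3 was called under every alternative, with log2 fold changes from -2.97 to -2.61. Itga6 ranged from -0.74 to -0.48 without 1 library and passed with sample quality weights (-0.75, adjusted p = 0.0243) and with DESeq2 and the block (-0.62, adjusted p = 0.00560), against adjusted p-values of 0.0731 to 0.407 elsewhere; the cause was not tested.

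Of the gene lists, 10 passed as planned, 13 with the replicate block, 6 to 13 without 1 library, 0 with an estimated correlation (also 0 with the block) and 0 with fry, or 2 with fry and the block (G2 and mitosis, S phase and replication). Sample quality weights ended the calls of 4 lists (cholesterol synthesis, interferon response, leukocyte markers, unfolded protein and integrated stress response) and added 3, the higher filter ended 2 (extracellular proteases, interferon response) and added 2, edgeR ended 1 (interferon response) and added 4, no filter added 3 and quantile scaling 1. Leaving out both replicate 3 libraries ended 1, extracellular proteases, with or without the block, and added 2 with it. The estimated correlations ran from 0.0103 for extracellular proteases to 0.90 for the interferon list among the lists lost, so their size alone does not account for every loss; the cause was not tested. The median of the interferon response list ranged from -0.00446 to 1.39 without 1 library, lowest without control replicate 2, which had the lowest score. The lists for G2 and mitosis, S phase and replication, hemidesmosome and focal adhesion, and luminal keratins and junctions, 4 in all, were called whichever library was left out. Lists were not tested with DESeq2, or with edgeR and the block. Depth limits what can be said of genes near 3 reads per library.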

Other observations

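The lists, the tests on lysosomal and amino acid genes, and the tests on Nrcam and Dnajb9 were chosen after the gene results were seen, and the values of the lists without their called genes, or without Ctsd, were predicted before they were computed. The test on macrophage RNA and its bounds were set after its values had been seen, and the bound of the test on close pairs was changed after its result was seen.

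Genes of amino acid supply and one-carbon metabolism mostly had negative changes. Of 28 tested members of a list for these pathways 26 had negative changes, with a median log2 fold change of -0.64; 4 were called by limma (Slc7a3, Slc1a5, Slc7a5 and Mthfd2) and 13 with the replicate block. Cth, which makes cysteine, had 553 ± 193 in control and 199 ± 54.3 in a3a6KO. Bcat1, a branched-chain aminotransferase, had 609 and 273, Mthfd1l 516 and 288, and Shmt2 2791 and 1923. Cth, Bcat1, Mthfd1l and Shmt2 passed limma with the replicate block (adjusted p = 0.00747, 0.0106, 0.0204 and 0.0417) and not without it (0.0675, 0.0627, 0.0931 and 0.0704). The 24 members not called had a median of -0.52, and camera gave p = 4.94e-13 with the preset correlation, and p = 0.00588 with an estimated correlation. The list was drawn up after the gene results were seen, and the 24 still held 9 members that passed with the block, so these p-values decide nothing about a group change; 10 of the 28 genes were also in a list fixed beforehand.

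Lysosomal genes mostly had positive changes. Of 34 tested members 33 had positive changes, with a median of 0.33, and none was called by limma; Ctsd, the protease cathepsin D, had 40193 in control and 79767 in a3a6KO (adjusted p = 0.0969; 0.0216 with the replicate block). Psap had 14651 and 19469, Ctsb 20561 and 27267, and Neu1 387 and 572. Without Ctsd the 33 other members had a median of 0.32 (camera p = 3.57e-11; p = 0.0340 with an estimated correlation), values that decide nothing about a group change, since this list too was drawn up after the gene results were seen. Of the 34 genes 2 were also in a fixed list. Macrophages express them too, and the leukocyte score was higher in a3a6KO in all 4 replicate pairs. The summed mean values of the 10 tested leukocyte markers rose by 0.478% of the summed rise of the lysosomal genes (317 against 66361). Most of the latter sum is the rise of Ctsd. The ratio of such markers to lysosomal RNA in macrophages was not measured, and the bounds were set after the values were seen. That share therefore decides nothing, macrophage RNA stays open as a source, and other sources were not tested.

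The joint rise of Nrcam and Dnajb9 was weighed against a local cause; RNA of other cell types as a source is not weighed here and stays open. Both were the higher genes with the smallest p, and 0.0348% of all pairs of tested genes lie as close together; since that value was computed for a pair already noticed, it decides nothing about independent rises of unrelated genes, which stay open. Whether a change of the genome near both genes, such as an inserted or linked sequence carried by the a3a6KO animals, is a candidate cause cannot be told apart from shared regulation of the region or from independent rises: the 37 called genes other than Itga3 held 1 pair within 1 Mb, and 0.681 of 10000 random draws held as many (mean 1.15), a test in which 1 pair cannot stand out. Reads or genotypes of the region would be needed, and a regulatory effect of the a3a6KO genotype stays open.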
